A study of Homo sapiens with 84 samples.

How the data were processed

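Gene expression was measured on 84 Illumina bead arrays in 8 established human lymphoma cell lines. Every line was treated with the solvent DMSO or with PQR309, which the labels' protocols describe as a dual PI3K/mTOR inhibitor, and arrays were made at 4, 8 and 12 h. RIVA, TMD8, SUDHL2 and U2932 were also treated with idelalisib, duvelisib or ibrutinib at the same times; OCILY1, OCILY18, DOHH2 and SUDHL10 were not. The first 4 lines are commonly classed as activated B-cell-like lymphoma and the other 4 as germinal-centre B-cell-like, a class the labels do not state. The labels give 1 array per line, time and treatment, no dose, and no statement on whether cultures were separate, so the p-values measure the spread between cell lines, and the number of lines limits the precision. RNA was extracted with a column kit and biotin-labelled for the arrays, per the labels' protocols.

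The authors deposited a normalized table and a raw table, and per the submitters' processing notes GenomeStudio was used, with no version given. The deposited normalized values are on a log2 scale and equal those of the series matrix, with a maximum difference of 0. The authors normalized them in 2 separate sets, the 48 DMSO and PQR309 arrays (median 6.64) and the 36 arrays of the other inhibitors (median 6.66), so values were not compared across these sets. The deposited raw table holds probe intensity, not background-subtracted and not normalized, for 81 arrays, with array medians from 78.3 to 139.7. For the other 3 arrays, OCILY1 with PQR309 at 4 h and with DMSO and PQR309 at 8 h, the deposited raw column holds a detection p-value where an intensity would stand. Of the 81 raw arrays, 54 rank the probes as the normalized table does. The other 27, with rank correlations of 0.873 to 0.973, are the DMSO and PQR309 arrays of the 4 lines given every inhibitor and the DMSO arrays of DOHH2, so that the raw table holds other arrays of these samples than the normalized table. Whether both sets of arrays were made from the same RNA is not stated.

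Separate sources of values were therefore used. Comparisons over all 8 lines used the authors' normalized values of the 48 arrays. Comparisons among the inhibitors used the 60 raw arrays of the 4 lines, with normexp background correction (offset 50), quantile normalization and log2 transformation in limma. The plan had named raw intensities for every comparison, and the change was made when the tables were found to hold different arrays, before any calls were compared. Of 47231 probes, 30113 carried 1 gene symbol, 8 carried several and 17110 were left unnamed, and 0 symbols needed an update; 20046 different symbols were represented. The brighter 50% of probes by mean value were kept, and the brightest probe stood for each gene, which left 12440 genes for 8 lines and 12559 for 4 lines. In the 3 arrays with detection p-values, 39.0% to 40.2% of probes were detected. The highest level at the detection limit in these 3 arrays, 6.73, was used for the 48 arrays. The 60 raw arrays have no detection p-values, so the level that leaves the same share of probes, 6.27, stood in for a limit there. By these levels 0 named genes lay below the limit on every array of a group. A single array above the limit is enough for this, so it does not show detection throughout a group. In the 48 arrays the brighter 50% of probes began at a mean of 6.645. That lies under the limit of 6.73, so genes near background could be kept. The arrays name no genome build, so no coordinates are given, and 0 per-sample columns were left unused by both the comparisons and their alternatives.

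Lines were the independent samples. For the 8 lines, drug minus DMSO was taken within a line and time and averaged over the 3 times (n = 8), or tested at a single time, and limma gave moderated tests. The 4 lines were fitted together as 20 line means of 5 treatments with the line as a block (n = 4). Pairing by line follows from the labels' line names; after removal of each treatment's mean, the profiles of a line under DMSO and PQR309 correlated across genes at 0.925 to 0.954 in the 8 lines, and any 2 treatments of a line correlated at 0.877 to 0.980 in the 4 lines. Genes are not independent replicates, so these correlations carry no p. Adjusted p-values are Benjamini-Hochberg, two-sided, with a threshold of 0.05. The software was R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.

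The following were fixed before the data were examined: 26 gene lists, the tests, and the rule for naming genes. The lists cover FOXO targets, cholesterol synthesis, fatty acid synthesis, ATF4 targets, glycolysis, ribosome biogenesis, MYC-linked metabolism, ribosomal proteins, G1/S genes, G2/M genes, histones, NF-kB targets, early B-cell receptor genes, STAT3 targets, interferon genes, lysosome and autophagy genes, B-cell identity, plasma cell genes, the BCL2 family, the PI3K pathway, the unfolded protein response, markers of the activated and of the germinal-centre class, and T-cell, myeloid and stromal markers. The rule named, for PQR309 over the 3 times, the 10 largest rises and 10 largest falls that passed in the same direction in all 8 lines, and up to 4 passing members of each list (2 of smallest p where none passed). It named 3 rises and 3 falls at each single time, and up to 5 of each in every other comparison (3 of smallest p where none passed). It also named the target genes of the inhibitors. A list of heat shock genes was added after the named falls were seen.

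Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 26 lists, with an estimated correlation and fry beside it. Tests were tried on simulated data in which 200 genes were moved. Each gene was drawn independently of the others, so the simulations hold no correlation between genes. The shares of recovered and false calls and the list test below therefore apply to independent genes, and may differ in the real arrays. For PQR309 over the 3 times, limma recovered 88.1% of genes moved 1.3-fold and 100% of those moved 2-fold, and 3.05% of the calls were false. For PQR309 in the 4 lines it recovered 64.2% and 98.5%, and for duvelisib against idelalisib at 4 h 14.9% and 89.4%. For the DMSO line sets it recovered 50.7% of genes moved 2-fold and 84.8% of those moved 4-fold. The share of false calls differed between tests. It was 1.905% for duvelisib against idelalisib at 4 h, 5.65% for PQR309 in the 4 lines, 7.65% for PQR309 at 4 h and 8.20% for the DMSO line sets. With 1 list moved 1.1-fold, camera found that list, and 1 unmoved list also passed. Alternatives tried were other background, scaling, filter and probe choices, other sources of values, no pairing, fits of only the treatments compared, and leaving out each line or time; other splits of the lines were also run.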

Results

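The series asked how 8 lymphoma cell lines respond to PQR309, per its title and labels, and 4 of the lines were also given drugs against single parts of the same signalling pathway. Idelalisib is a PI3K delta inhibitor, duvelisib a PI3K delta and gamma inhibitor, and ibrutinib an inhibitor of BTK, the kinase that carries B-cell receptor signals. There were 24 DMSO arrays and 24 PQR309 arrays from 8 lines, and 12 arrays for each of the other 3 inhibitors from 4 lines, at 4, 8 and 12 h. Each line, time and treatment had 1 array, and the number of lines limits the precision. Values below are log2 differences between treatment and DMSO within a line, with limma's moderated standard error (SE), and adjusted p-values are from limma. With 8 lines the SE rests on the spread across lines, and n is the number of lines. In the joint fit of the 4 lines the SE pools the residual spread of all 5 treatments. A gene there has the same SE for every inhibitor, which is not the spread of that inhibitor's own effect between lines.

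With PQR309, over the 3 times and 8 lines, the largest rise was that of PIM1, a survival kinase, by 1.01 ± 0.16 (SE, n = 8, adjusted p = 0.00204), from a mean log2 level of 9.18 with DMSO to 10.19. The chemokine receptor gene CXCR4 rose by 0.99 ± 0.14, and YPEL3 and KLHL24, both known to be raised by FOXO factors, rose by 0.87 ± 0.14 and 0.84 ± 0.09. RUBCNL, an autophagy regulator, rose by 0.85 ± 0.14 and RMI2, a member of a DNA repair complex, by 0.79 ± 0.07. RASSF6, SUN2, FGD3 and RCSD1 rose by 0.69 to 0.75. The largest falls were in the inflammatory cytokine TNF (-0.90 ± 0.27) and the nucleolar gene CCDC86 (-0.82 ± 0.09). Next came the chaperones HSPA1B (-0.81 ± 0.14), HSPA8 (-0.74 ± 0.09) and HSPH1 (-0.74 ± 0.09). The chemokine gene CCL3L3 (-0.71 ± 0.19), the nucleolar helicase DDX21 (-0.69 ± 0.08) and the hexokinase HK2 (-0.68 ± 0.10) fell. PAK1IP1 (-0.67 ± 0.09) and the phosphatase PTPN6 (-0.66 ± 0.09) also fell. These 20 genes were picked from those that moved the same way in all 8 lines, so that agreement is not a result. The rule left out falls of similar size in which a line went the other way, such as FASN (0.17 in SUDHL2) and DDIT4 (0.045 in TMD8). Across 12440 genes, 1550 rose and 1745 fell (3295 in all, and 4793 at an unadjusted p under 0.05). Without pairing by line limma called 0 genes (441 at an unadjusted p under 0.05), and with raw intensities in 6 lines it called 1304, of which 1193 were shared. The fall of TNF (adjusted p = 0.0338) did not pass without RIVA (adjusted p = 0.0714), SUDHL10 (0.0632) or U2932 (0.0834), nor that of CCL3L3 without RIVA (0.0517) or TMD8 (0.0511).

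**Figure D1:**
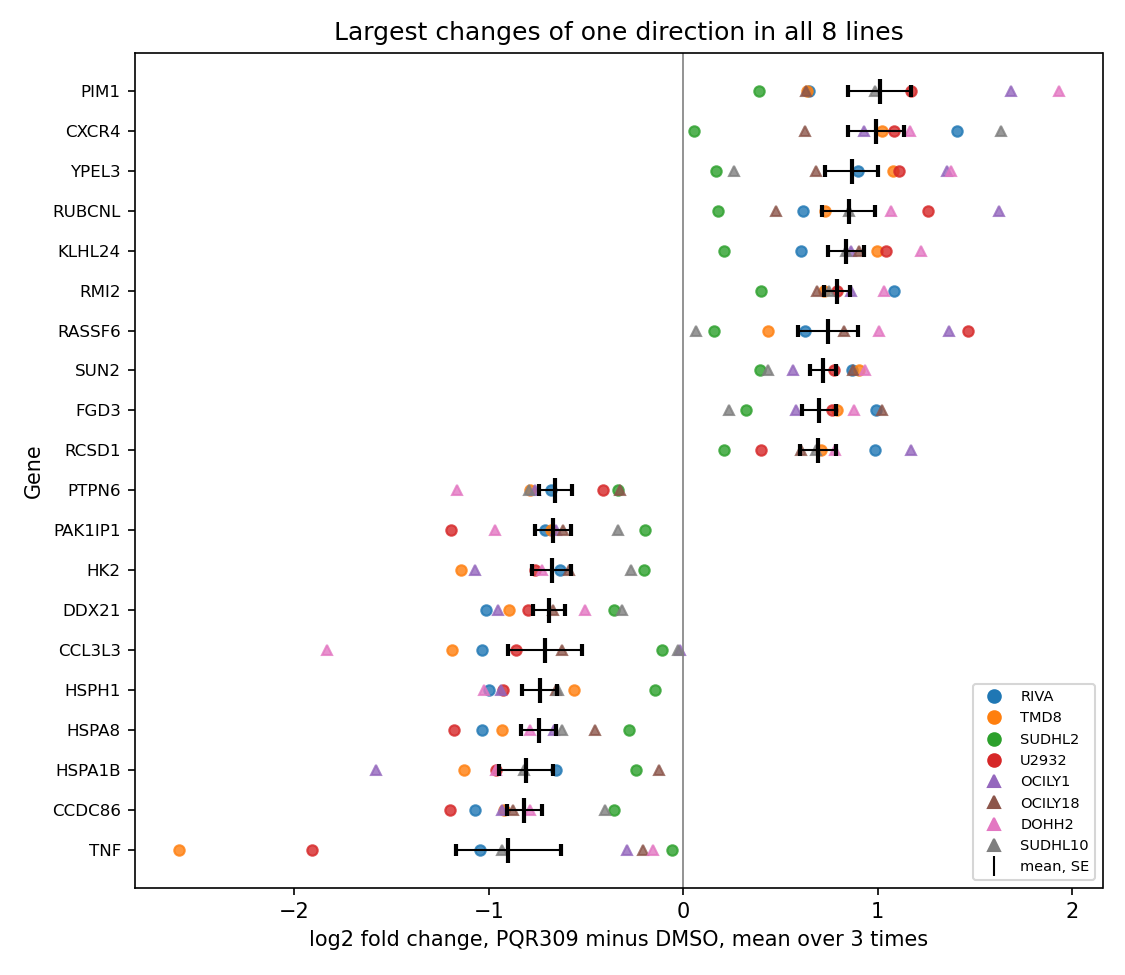
Log2 difference between PQR309 and DMSO (mean of 3 times) for the 10 largest rises and 10 largest falls, with 1 symbol per cell line (circles for the 4 lines given every inhibitor, triangles for the 4 given PQR309 only) and a bar for the mean with its SE. PIM1, at a mean of 1.01, and TNF, at -0.90, mark the ends of the range.

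Genes that FOXO factors are known to raise, and that PI3K signalling holds down, rose as a group. Of 28 measured FOXO targets 14 rose and 0 fell (15 and 0 adjusted over the list alone), among them HBP1 (0.68 ± 0.09) and YPEL5 (0.62 ± 0.08). Genes that assemble ribosomes went down, with 0 of 39 rising and 28 falling (0 and 30 adjusted over the list alone), including LYAR (-0.68 ± 0.10), RRS1 (-0.61 ± 0.08) and NOP16 (-0.57 ± 0.12). The list of MYC-linked nucleotide, polyamine and mitochondrial genes had 1 rise and 22 falls among 29 (1 and 23 adjusted over the list alone). TOMM40 was at -0.65 ± 0.10, SRM at -0.53 ± 0.11 and CTPS1 at -0.49 ± 0.08. Camera gave adjusted p = 2.68e-08 for the FOXO targets, 3.93e-12 for ribosome biogenesis and 2.74e-09 for the MYC-linked list. Each of these had adjusted p = 0.423 with an estimated correlation. Of the 12 lists that passed with the preset value, 0 passed with an estimated one, while fry called 12 lists. Fry asks whether a list moved at all, and camera whether it moved more than the other genes. These counts do not say whether the same lists passed. Among 50 ribosomal protein and elongation factor genes, 10 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00146, and adjusted p = 0.423 with an estimated correlation). RPL14 (0.36 ± 0.05) and RPL13A (0.33 ± 0.07) rose, and RPL29 (-0.62 ± 0.11) and RPS7 (-0.36 ± 0.07) fell.

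Metabolic gene groups were lower. In cholesterol synthesis, 1 of 19 genes rose and 10 fell (1 and 10 adjusted over the list alone), with ACAT2 at -0.41 ± 0.09 and IDI1 at -0.36 ± 0.07. The synthase HMGCS1 was at -0.46 ± 0.10, a fall that did not pass without the 4 h arrays (adjusted p = 0.0553). In fatty acid synthesis, 1 of 14 rose and 7 fell (1 and 8 adjusted over the list alone). The fatty acid synthase FASN (-0.70 ± 0.15), the desaturase SCD (-0.40 ± 0.08) and the carboxylase ACACA (-0.34 ± 0.07) fell, while AACS rose by 0.27 ± 0.05. Among 29 glycolysis genes 1 rose and 11 fell (2 and 11 adjusted over the list alone), among them PGAM1 (-0.48 ± 0.09), LDHA (-0.45 ± 0.09) and TPI1 (-0.40 ± 0.10). By line the glycolysis median ran from -0.28 in DOHH2 to 0.0074 in SUDHL2. The raw arrays of the 4 lines given every inhibitor did not show this fall. There the glycolysis median with PQR309 averaged 0.0082 (SD 0.083) and lay above 0 in 2 of 4 lines. Among 33 ATF4 targets, which serve amino acid supply, 0 rose and 8 fell (0 and 8 adjusted over the list alone). They included the stress gene DDIT4 (-0.70 ± 0.15) and the amino acid carriers SLC1A5 (-0.42 ± 0.07) and SLC3A2 (-0.30 ± 0.07). Of 19 genes of the unfolded protein response 1 rose and 12 fell (2 and 14 adjusted over the list alone). SDF2L1 was at -0.64 ± 0.09, MANF at -0.59 ± 0.11 and the chaperone HSPA5 at -0.50 ± 0.11. Camera gave adjusted p = 0.00129 for cholesterol synthesis, 0.0461 for fatty acid synthesis, 0.00943 for glycolysis, 0.00146 for ATF4 targets and 0.000405 for the unfolded protein response. These calls were lost when the correlation was estimated, with adjusted p = 0.423 with an estimated correlation for the cholesterol, fatty acid and unfolded protein lists, 0.479 for glycolysis and 0.637 for ATF4 targets.

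Genes of the G2 and mitotic phases were higher: 22 of 45 rose and 1 fell (30 and 1 adjusted over the list alone). The rises included NUSAP1 (0.41 ± 0.05), ASPM (0.41 ± 0.05), HMMR (0.40 ± 0.06) and the cyclin CCNB2 (0.38 ± 0.07). Camera gave adjusted p = 3.23e-09, and adjusted p = 0.423 with an estimated correlation. Of 16 histone genes 6 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 0.00161, and adjusted p = 0.423 with an estimated correlation), with H2AC18 at 0.30 ± 0.05. Of 37 G1/S genes 2 rose and 7 fell (2 and 9 adjusted over the list alone; adjusted p = 0.126). The phosphatase CDC25A (-0.44 ± 0.08) and the replication fork gene TIPIN (-0.39 ± 0.05) were among the falls. In the BCL2 family of apoptosis regulators 4 of 15 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.548). The death promoters HRK (0.63 ± 0.16) and BMF (0.46 ± 0.10) rose and BID (-0.40 ± 0.08) fell.

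Of 21 early B-cell receptor genes 0 rose and 3 fell (0 and 3 adjusted over the list alone), namely DUSP2 (-0.51 ± 0.12), JUNB (-0.21 ± 0.05) and SPRED1 (-0.21 ± 0.04). That share of falls is near the share among all genes (1745 of 12440, with 1550 rises). The list's median effect averaged -0.11 and lay above 0 in 1 of 8 lines. Camera gave adjusted p = 0.0244, a call lost with an estimated correlation (adjusted p = 0.423). Among 33 NF-kB targets 3 rose and 5 fell (4 and 9 adjusted over the list alone; adjusted p = 0.0511). The inhibitor NFKBIE (-0.57 ± 0.14) and PLEK (-0.54 ± 0.12) fell and the homing receptor CCR7 (0.51 ± 0.12) rose. The B-cell identity list went both ways, with 7 of 30 rising and 5 falling (7 and 5 adjusted over the list alone; adjusted p = 0.562). Its median (-0.0085) and mean (0.023) differed in sign. CD37 (0.65 ± 0.11) and the coactivator POU2AF1 (0.51 ± 0.08) rose, and the transcription factor SPIB fell (-0.66 ± 0.15). MS4A1, which encodes CD20, was at -0.51 ± 0.14, a call lost when the probes of a gene were averaged. In the STAT3 list 3 of 17 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.548), with PIM2 at 0.53 ± 0.09 and the receptor IL4R at 0.38 ± 0.09. The median of that list lay below 0 while its mean and its test lay above.

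The remaining lists did not pass camera. Lysosome and autophagy genes had 10 rises and 4 falls among 42 (10 and 4 adjusted over the list alone; adjusted p = 0.0956), including the autophagy kinase ULK1 (0.42 ± 0.06) and ATG14 (0.31 ± 0.06). Interferon genes had 4 rises and 3 falls among 36, with ISG20 at 0.60 ± 0.08, SAMD9 at 0.28 ± 0.04 and LAP3 at -0.29 ± 0.05. PI3K pathway genes had 4 rises and 2 falls among 24, with the pathway inhibitor PIK3IP1 at 0.37 ± 0.06, TSC1 at 0.25 ± 0.05 and PIK3CB at -0.22 ± 0.03. Of the named target genes, PIK3CB was among these falls. PIK3CG was among the rises, with line values from -0.06 in OCILY1 to 1.05 in DOHH2. PIK3CD was at 0.17 ± 0.06, MTOR at -0.10 ± 0.05 and BTK at -0.0091 ± 0.04, and these did not pass. Of 12 plasma cell genes 1 rose and 2 fell, with FKBP11 at -0.33 ± 0.08. Markers of the activated class had 5 rises and 2 falls among 17, with ETV6 at 0.32 ± 0.06. Markers of the germinal-centre class had 4 rises and 2 falls among 17. MME, which encodes CD10, was at 0.67 ± 0.14, GCSAM at 0.51 ± 0.12 and SSBP2 at 0.30 ± 0.04. Among markers of other cells, 0 of 6 T-cell, 0 of 4 myeloid and 0 of 3 stromal genes passed in limma. LCK was at -0.088, FCGR3A at 0.10 and PECAM1 at 0.091.

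**Figure D2:**
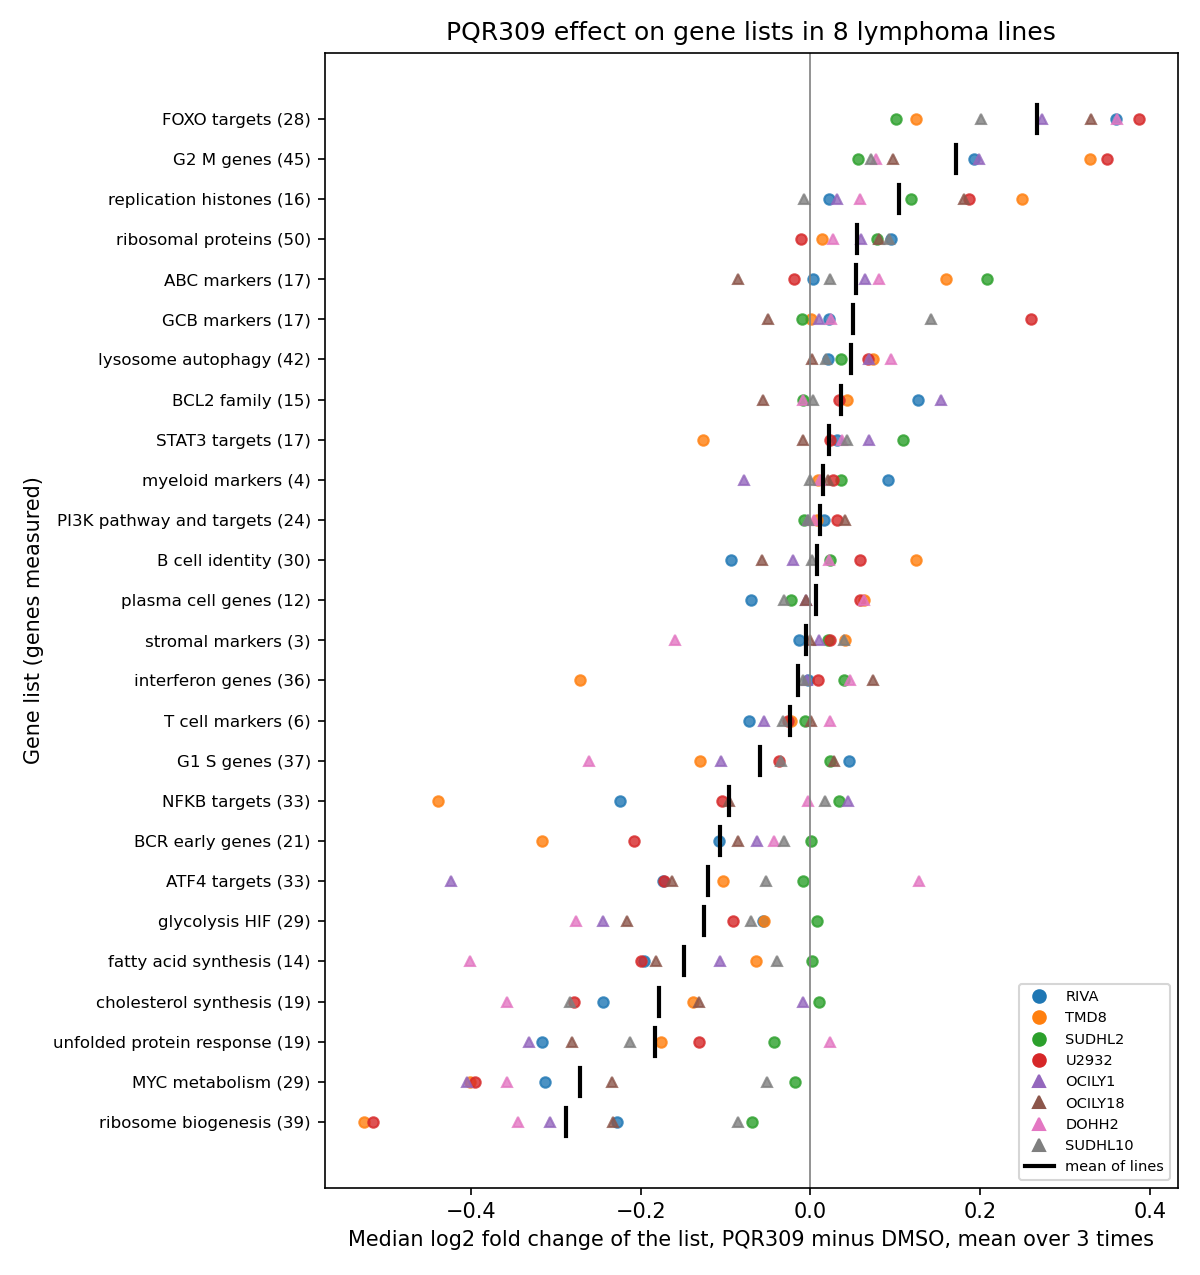
Median log2 difference between PQR309 and DMSO over the members of each gene list, with 1 symbol per cell line and a bar for the mean of the 8 lines. FOXO targets and G2/M genes lie above 0 in 8 of 8 lines and ribosome biogenesis genes in 0 of 8.

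At 4 h PQR309 already raised PIM1 (1.03 ± 0.11), CXCR4 (0.89 ± 0.17) and the FOXO target HBP1 (0.79 ± 0.08). It lowered TNF (-0.94 ± 0.25), PTMA (-0.88 ± 0.22) and the HSP90 partner PTGES3 (-0.83 ± 0.12). At 8 h CXCR4 (1.1 ± 0.18), RMI2 (0.93 ± 0.09) and YPEL3 (0.90 ± 0.15) led the rises. HSPA1B (-1.11 ± 0.16), FASN (-0.99 ± 0.10) and CCDC86 (-0.94 ± 0.12) led the falls. At 12 h PIM1 (1.15 ± 0.21), YPEL3 (1.11 ± 0.17) and KLHL24 (1.08 ± 0.13) rose most. FABP5 (-0.90 ± 0.15), RPL29 (-0.87 ± 0.17) and the mitochondrial chaperone HSPE1 (-0.83 ± 0.13) fell most. FOXO targets had 13, 12 and 14 rises of 28 at 4, 8 and 12 h (14, 13 and 17 adjusted over the list alone) and 0 falls at each time. Camera gave adjusted p of 2.49e-08, 4.82e-08 and 7.92e-09 (adjusted p = 0.198, 0.295 and 0.378 with an estimated correlation). Limma called 2155 genes at 4 h (980 up and 1175 down), 1988 at 8 h (932 and 1056) and 2552 at 12 h (1308 and 1244). The count at 4 h was 1303 without RIVA, 1326 without OCILY18 and 1433 without SUDHL10. That at 8 h was 1216 without U2932 and 1235 without OCILY1, and that at 12 h was 1637 without U2932. Without pairing by line limma called 1, 0 and 0 genes (781, 568 and 538 at an unadjusted p under 0.05), and with raw intensities 212 and 94 in 6 lines and 853 in 7.

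The PQR309 effect itself changed between 4 and 12 h. It moved down for glycolysis genes, of which 10 of 29 fell and 0 rose (13 and 1 adjusted over the list alone), among them GPI (-0.88 ± 0.10) and PKM (-0.81 ± 0.15). Their list median effect averaged 0.013 (SD 0.06, n = 8) at 4 h and -0.28 (SD 0.20) at 12 h. G1/S genes went the same way, with 14 of 37 falling and 0 rising (20 and 0 adjusted over the list alone). Their list median effect averaged 0.067 (SD 0.06, n = 8) at 4 h and -0.19 (SD 0.21) at 12 h. In the MYC-linked list 13 of 29 fell and 0 rose (18 and 0 adjusted over the list alone). HSPE1, one of that list, had the largest shift of the named genes (-1.11 ± 0.09). FABP5 (-0.94 ± 0.07) and the HSP90 partner CACYBP (-0.81 ± 0.11) also shifted down. With DMSO alone HSPE1 and other genes of the MYC-linked list rose between 4 and 12 h, as given below. Such a rise in the DMSO arrays enters these shifts, so they are not changes of the PQR309 arrays alone. How much came from each treatment was not tested. The effect moved upward for RPL21P28 (0.88 ± 0.10), FCMR (0.73 ± 0.16), YPEL5 (0.72 ± 0.11), PHYH (0.71 ± 0.16) and LTB (0.78 ± 0.21). Camera gave adjusted p = 1.06e-05 for glycolysis, 8.49e-11 for G1/S genes and 1.92e-12 for the MYC-linked list, and adjusted p = 0.482, 0.521 and 0.220 with an estimated correlation. Ribosome biogenesis (1 rise, 5 falls; adjusted p = 0.0113) and interferon genes (1 rise, 3 falls; adjusted p = 0.0187) passed too, each with adjusted p = 0.795 with an estimated correlation. Limma called 1292 genes (606 up and 686 down), but 722 without RIVA, 748 without OCILY18, 777 without SUDHL2, 836 without SUDHL10 and 839 without U2932. Without pairing by line it called 0 (271 at an unadjusted p under 0.05), and with raw intensities in 6 lines 0 (1058 at an unadjusted p under 0.05).

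**Figure D3:**
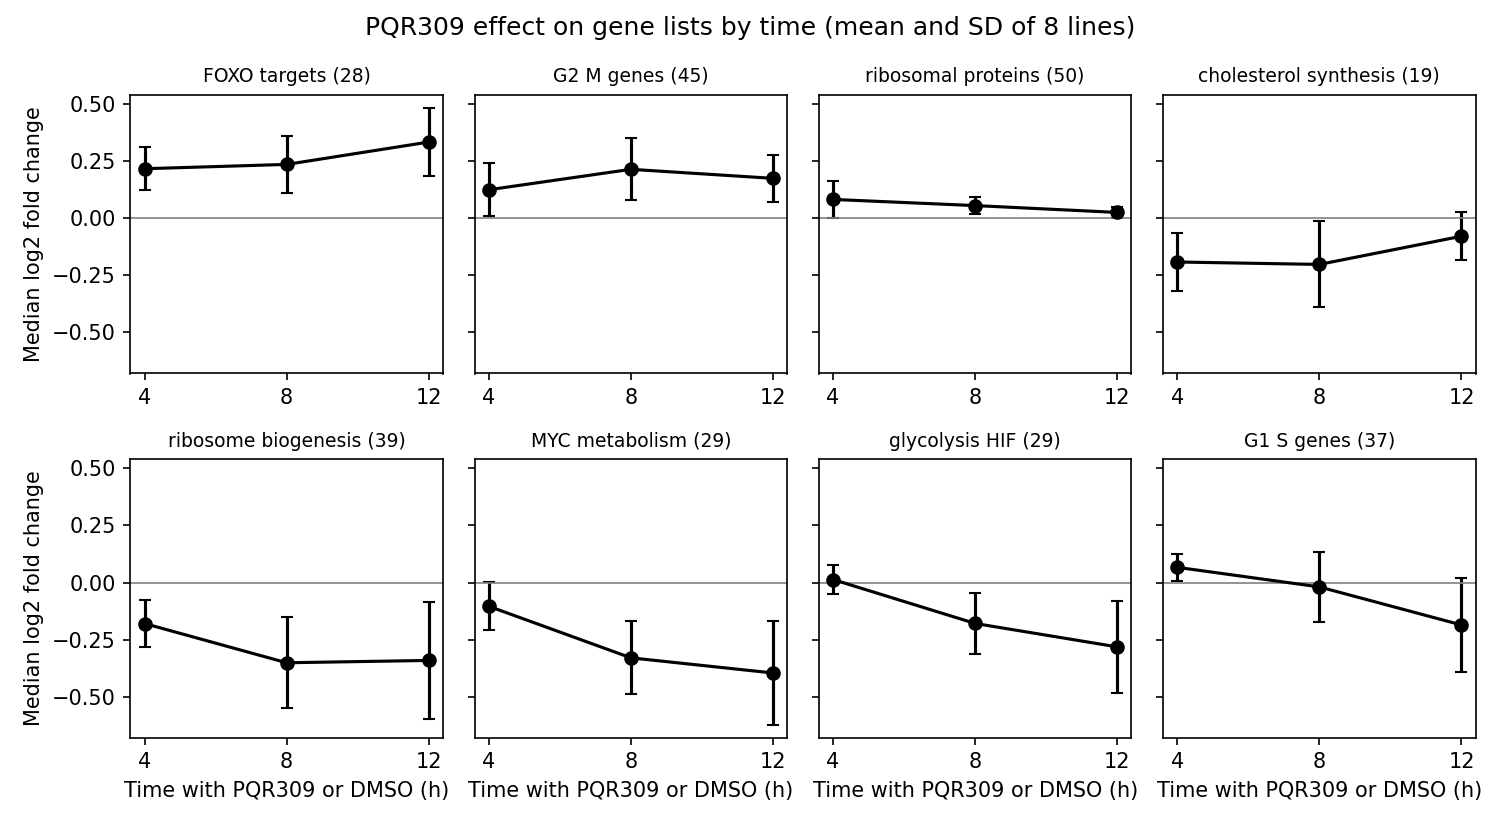
Mean over 8 lines of the median log2 effect of PQR309 on 8 gene lists at 4, 8 and 12 h, with the SD between lines as the error bar. The G1/S list goes from 0.067 at 4 h to -0.19 at 12 h, and FOXO targets stay above 0 at each time.

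The lines given every inhibitor were set against those given PQR309 only, 4 against 4, a split that coincides with the common class of the lines. The 3 genes of smallest p were the transcriptional inhibitor ID3, whose PQR309 effect was higher by 0.60 ± 0.11 in the lines given every inhibitor, LPXN (0.39 ± 0.08) and ASF1B (0.41 ± 0.08). These did not pass. Limma called 0 of 12440 genes (543 at an unadjusted p under 0.05; smallest adjusted p = 0.998). Several lists passed camera on the difference, G2/M genes (median difference 0.12; adjusted p = 1.68e-09), NF-kB targets (-0.17; 4.70e-05) and FOXO targets (-0.10; 0.00946) among them. Each of these 3 had adjusted p = 0.733 with an estimated correlation.

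With DMSO alone, PLBD1 was higher by 2.01 ± 0.23, the IL10 receptor gene IL10RA by 1.70 ± 0.20 and the histone gene H2BC12 by 2.64 ± 0.32 in the lines given every inhibitor than in the others. None of these 3 passed (adjusted p = 0.218). Limma called 0 genes (787 at an unadjusted p under 0.05), and 3 when U2932 was left out. Markers of the activated class had a median difference of 1.32 (1 rise adjusted over the list alone, of 17; camera adjusted p = 2.18e-08), histone genes 0.69 (8 rises of 16 adjusted over the list alone; 1.08e-08) and NF-kB targets 0.58 (0 adjusted over the list alone; 3.34e-07). The adjusted p with an estimated correlation was 0.162 for the first 2 lists and 0.398 for the third. Markers of the germinal-centre class had a median difference of -0.15 (adjusted p = 0.251).

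Time in culture without drug also changed expression. Between 4 and 12 h with DMSO the chaperones HSPA1B (1.0 ± 0.12), HSPH1 (0.86 ± 0.10), HSPA8 (0.73 ± 0.11), STIP1 (0.72 ± 0.11) and HSPE1 (0.69 ± 0.07) rose in 8 of 8 lines. The glucocorticoid-response gene TSC22D3 fell by 1.03 ± 0.10, the sterol regulator INSIG1 by 0.85 ± 0.16, the cold-response gene CIRBP by 0.83 ± 0.10, JUND by 0.79 ± 0.16 and LPIN1 by 0.70 ± 0.11. In the MYC-linked list 5 of 29 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.000395). In the FOXO list 0 rose and 2 fell (0 and 5 adjusted over the list alone; adjusted p = 0.0218). Both had adjusted p = 0.897 with an estimated correlation. Limma called 950 genes (515 up and 435 down), but 339 without RIVA, 558 without DOHH2, 559 without U2932, 615 without SUDHL10 and 617 without SUDHL2. Without pairing by line it called 0 (557 at an unadjusted p under 0.05), and with raw intensities in 8 lines 22, of which 16 were shared.

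In the 4 lines given every inhibitor, PQR309 raised YPEL3 (1.18 ± 0.16, n = 4), the MAX partner MXD3 (1.1 ± 0.19), CXCR4 (1.1 ± 0.21), the death promoter HRK (1.05 ± 0.20) and KLHL24 (1.01 ± 0.12). It lowered TNF (-1.66 ± 0.46), CCL3L3 (-1.22 ± 0.25), the lymphotoxin gene LTA (-1.16 ± 0.31), MIR155HG, the host gene of a B-cell microRNA (-1.14 ± 0.23), and FASN (-1.12 ± 0.15). FOXO targets had 11 rises and 0 falls of 27 (16 and 1 adjusted over the list alone; camera adjusted p = 1.23e-07). That call held, with adjusted p = 0.0241 with an estimated correlation. Ribosome biogenesis had 0 rises and 26 falls of 39 (0 and 30 adjusted over the list alone; 2.61e-21), the MYC-linked list 1 and 17 of 29 (1 and 21; 5.86e-13) and G2/M genes 25 and 0 of 45 (33 and 1; 6.49e-14). Each of these had adjusted p = 0.0612 with an estimated correlation. NF-kB targets had 1 rise and 10 falls of 30 (3 and 15 adjusted over the list alone; adjusted p = 0.000349, and adjusted p = 0.312 with an estimated correlation). By line their median was -0.63 in TMD8, -0.24 in RIVA, -0.23 in U2932 and 0.04 in SUDHL2. Early B-cell receptor genes had 0 rises and 5 falls of 22 (0 and 8 adjusted over the list alone; 0.00268, and adjusted p = 0.283 with an estimated correlation). Limma called 1696 of 12559 genes (907 up and 789 down), but 294 without TMD8, 385 without U2932, 818 without RIVA, 943 without the 8 h arrays and 1054 without the 12 h arrays. It called 0 in a fit of these 2 treatments alone (3068 at an unadjusted p under 0.05), 1 without the line as a block, 0 with arrays scaled to a common median (1050 at an unadjusted p under 0.05) and 244 with the authors' normalized values, of which 160 were shared.

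Idelalisib raised CXCR4 (0.84 ± 0.21, n = 4), CYTH2 (0.79 ± 0.17), MXD3 (0.77 ± 0.19), YPEL3 (0.76 ± 0.16) and TNK2 (0.66 ± 0.17). It lowered LTA (-1.18 ± 0.31), MIR155HG (-1.11 ± 0.23), the transcription factor BATF (-1.01 ± 0.17), NFKBIE (-0.99 ± 0.19) and PLEK (-0.99 ± 0.23). NF-kB targets had 0 rises and 7 falls of 30 (0 and 18 adjusted over the list alone; camera adjusted p = 2.65e-09), ribosome biogenesis 0 and 16 of 39 (0 and 25; 7.37e-18) and G2/M genes 9 and 0 of 45 (25 and 0; 6.84e-11). These had adjusted p = 0.104, 0.0973 and 0.0973 with an estimated correlation. By line the NF-kB median was -0.89 in TMD8, -0.31 in RIVA, -0.14 in U2932 and -0.08 in SUDHL2. FOXO targets had 5 rises and 0 falls of 27 (6 and 1 adjusted over the list alone; adjusted p = 0.00119, and adjusted p = 0.0973 with an estimated correlation). Limma called 586 genes (345 up and 241 down), but 0 without RIVA, 0 without TMD8, 214 without U2932 and 12 without the 8 h arrays. It called 0 in a fit of these 2 treatments alone (1979 at an unadjusted p under 0.05), 0 without the line as a block (133) and 0 with median scaling (486).

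Ibrutinib raised YPEL3 (0.94 ± 0.16, n = 4), MXD3 (0.92 ± 0.19), VAMP2 (0.86 ± 0.22), the calcium pump ATP2A3 (0.76 ± 0.18) and the lipase PNPLA2 (0.76 ± 0.17). It lowered LTA (-1.38 ± 0.31), MIR155HG (-1.24 ± 0.23), CCL3L3 (-1.19 ± 0.25), NFKBIE (-1.13 ± 0.19) and the stress-response phosphatase subunit PPP1R15A (-1.10 ± 0.12). NF-kB targets had 0 rises and 7 falls of 30 (1 and 17 adjusted over the list alone; camera adjusted p = 5.67e-08), ribosome biogenesis 0 and 11 of 39 (0 and 22; 1.74e-13), G2/M genes 7 and 0 of 45 (23 and 0; 2.09e-09) and FOXO targets 3 and 0 of 27 (4 and 0; 0.00426). These had adjusted p = 0.229 with an estimated correlation for the first and 0.220 for the others. Limma called 373 genes (150 up and 223 down), but 2 without RIVA, 2 without TMD8, 3 without U2932, 1 without the 8 h arrays and 171 without the 8 h arrays of SUDHL2. It called 66 with no filter on dim probes, 0 in a fit of these 2 treatments alone (2130 at an unadjusted p under 0.05), 0 without the line as a block (171) and 0 with median scaling (650).

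Duvelisib raised ALDH6A1, a valine catabolism enzyme (0.45 ± 0.07, n = 4, adjusted p = 0.0343), and the nuclear receptor gene NR2C1 (0.37 ± 0.05, adjusted p = 0.0162), each higher in 4 of 4 lines. These 2 were the genes that limma called (1832 at an unadjusted p under 0.05). For its group medians, NF-kB targets lay at -0.38 (0 rises and 17 falls of 30 adjusted over the list alone; camera adjusted p = 1.93e-09), ribosome biogenesis at -0.22 (0 and 19 of 39; 5.61e-17), FOXO targets at 0.16 (5 and 0 of 27; 0.000137) and G2/M genes at 0.15 (6 and 0 of 45; 1.81e-09). The adjusted p with an estimated correlation was 0.134 for NF-kB targets and 0.102 for the others. By line the NF-kB median was -0.86 in TMD8, -0.24 in RIVA, -0.18 in U2932 and -0.05 in SUDHL2. The count was 0 without RIVA, 0 without TMD8, 108 without SUDHL2, 2 without U2932 (of which 1 was among the original 2), 1 without the 4 h arrays, 0 without the 8 h arrays, 45 without the 12 h arrays and 0 without the 8 h arrays of SUDHL2. It was 0 in a fit of these 2 treatments alone (1178 at an unadjusted p under 0.05), 0 without the line as a block (57), 0 with median scaling (450) and 0 with averaged probes.

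**Figure D4:**
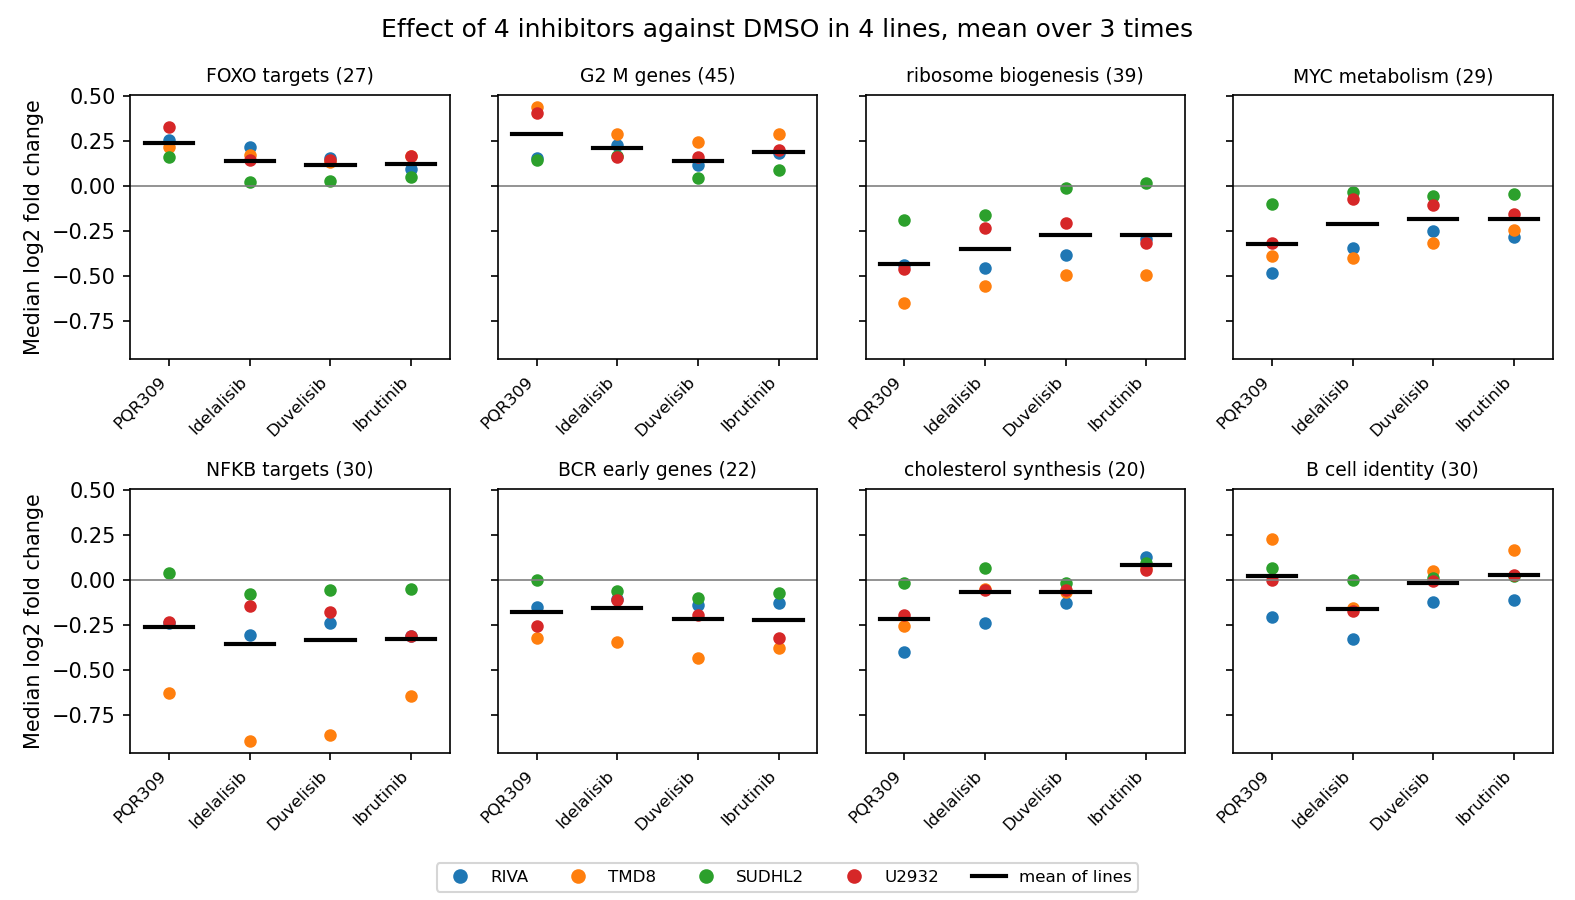
Median log2 difference from DMSO (mean of 3 times) for 8 gene lists under 4 inhibitors, with 1 symbol per line for the 4 lines and a bar for their mean. Ribosome biogenesis genes average -0.43 with PQR309, -0.35 with idelalisib, -0.27 with duvelisib and -0.27 with ibrutinib.

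The inhibitors were also compared directly. Against idelalisib, PQR309 gave higher HLA-DMB, an antigen-loading gene (0.52 ± 0.09, n = 4), RMI2 (0.51 ± 0.09), UBALD2 (0.51 ± 0.08), the B-cell transcription factor EBF1 (0.43 ± 0.08) and ZCCHC7 (0.42 ± 0.07). It gave lower RAB23 (-0.47 ± 0.08), FBXO22 (-0.39 ± 0.07), TMEM38B (-0.35 ± 0.06) and DYNLL1 (-0.30 ± 0.05). Against ibrutinib it gave higher PPP1R15A (0.84 ± 0.12), PPP3CA-DT (0.62 ± 0.10), HLA-DMB (0.57 ± 0.09), UBALD2 (0.57 ± 0.08) and the mitotic phosphatase CDC25C (0.41 ± 0.07). The chaperone DNAJB1 was lower (-0.52 ± 0.09). B-cell identity genes were higher with PQR309 than with idelalisib (1 rise and 0 falls of 30, 7 and 0 adjusted over the list alone; camera adjusted p = 1.04e-09, and adjusted p = 0.0380 with an estimated correlation). Against DMSO, the median of that list averaged -0.16 (SD 0.14, above 0 in 1 of 4 lines) with idelalisib. It averaged 0.022 (SD 0.18) with PQR309, so the difference lay mainly in a lower value with idelalisib. The same idelalisib arrays enter every comparison with idelalisib. Cholesterol genes were lower with PQR309 than with ibrutinib (0 of 20 passed, 0 rises and 8 falls adjusted over the list alone; median -0.23; 5.67e-10, and adjusted p = 0.0187 with an estimated correlation). So were fatty acid genes (0 and 5 of 13 adjusted over the list alone; 0.000201, and adjusted p = 0.0187 with an estimated correlation). FOXO targets were higher with PQR309 than with ibrutinib (8 rises and 1 fall of 27 adjusted over the list alone), duvelisib (7 and 0) and idelalisib (3 and 0). These had adjusted p = 0.0237, 0.0296 and 0.0380 with an estimated correlation. Limma called 11 genes against idelalisib, 7 against ibrutinib and 0 against duvelisib (879 at an unadjusted p under 0.05). There UBALD2 (0.43 ± 0.08), USP11 (0.40 ± 0.08) and CDC25C (0.35 ± 0.07) had the smallest p. The 11 became 0 without any 1 of the 4 lines, without the 4 h or the 8 h arrays or in a fit of these 2 treatments alone, 23 without the 12 h arrays, of which 8 were among the 11, and 12 without the 8 h arrays of SUDHL2, of which 6 were. The 7 (6 up and 1 down) became 0 without RIVA, U2932 or the 8 h arrays, 4 without TMD8, of which 2 were among the 7, and 9 without SUDHL2 (3 up and 6 down), of which 1 was among the 7. They became 1 without the 4 h arrays, 41 without the 12 h arrays and 14 without the 8 h arrays of SUDHL2. They became 64 in a fit of these 2 treatments alone, 15 with the brightest 25% of probes and 4 with averaged probes, and the 11 became 7 with averaged probes. Both counts were 0 without the line as a block (31 and 49 at an unadjusted p under 0.05) and 0 with median scaling.

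Ibrutinib and idelalisib, which act on different enzymes, differed by 1 gene past the threshold: with ibrutinib relative to idelalisib, PPP1R15A was at -1.0 ± 0.12 (n = 4, adjusted p = 0.00450, lower in 4 of 4 lines). Cholesterol genes were higher with ibrutinib than with idelalisib (median 0.17; 0 genes passed over all genes or adjusted over the list alone; camera adjusted p = 6.53e-07, and adjusted p = 0.0451 with an estimated correlation). So were B-cell identity genes (0.15; 2 rises adjusted over the list alone; 3.65e-13, and adjusted p = 0.0397 with an estimated correlation). Relative to DMSO, the median of the B-cell identity list averaged 0.026 with ibrutinib and -0.16 with idelalisib. Against duvelisib, PPP1R15A was at -0.66 ± 0.12 with ibrutinib, DIPK2A at 0.30 ± 0.07 and TIPARP at -0.58 ± 0.15. There limma called 0 genes (427 at an unadjusted p under 0.05). The call of PPP1R15A against idelalisib (605 genes at an unadjusted p under 0.05) was lost without SUDHL2 (adjusted p = 0.148), U2932 (0.232) or TMD8 (0.168), where 1 other gene was called. The count was 0 without SUDHL2 or U2932, 0 without the line as a block (10), 0 in a fit of these 2 treatments alone (950) and 0 with median scaling or the authors' normalized values, and 2 without the 12 h arrays.

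Duvelisib and idelalisib are related in structure, and both link a purine to a bicyclic core through a short chiral amine. The core is a quinazolinone with fluorine and a propyl-derived linker in idelalisib and an isoquinolinone with chlorine and an ethyl-derived linker in duvelisib. At matched times, and at doses that the labels do not give, CLECL1 (0.29 ± 0.06, 95% interval 0.16 to 0.42), MYB (0.41 ± 0.09, 0.23 to 0.59) and EBF1 (0.31 ± 0.08, 0.15 to 0.47) were the genes of smallest p. Each was higher with duvelisib in 4 of 4 lines, and none of these 3 passed (adjusted p = 1). Limma called 0 genes (271 at an unadjusted p under 0.05). The 95% interval of the difference had a median half-width of 0.166, and for 97.7% of 12559 genes it lay within 0.5 log2 units of 0. With median scaling the half-width was 0.320 and the share 63.1%, and the median SD between lines was 0.278 against 0.118 after quantile normalization. B-cell identity genes were higher with duvelisib (median difference 0.097; 1 rise adjusted over the list alone; camera adjusted p = 1.43e-07, and adjusted p = 0.122 with an estimated correlation). Relative to DMSO, their list median averaged -0.017 with duvelisib and -0.16 with idelalisib. At 4 h DDX59 was at -1.21 ± 0.18, INTS1 at 0.63 ± 0.10 and TNS3 at 0.56 ± 0.09. At 8 h PPP1R15A was at -0.55 ± 0.08, TUBG1 at -0.44 ± 0.09 and MRPS18B at 0.47 ± 0.09. At 12 h VAMP8 was at -0.40 ± 0.08, SNORD13 at -0.43 ± 0.09 and CLECL1 at 0.36 ± 0.08. At each time limma called 0 genes (1720, 492 and 389 at an unadjusted p under 0.05), and 89 at 4 h when TMD8 was left out. In simulated data the test at 4 h recovered 14.9% of genes moved 1.3-fold, 50.7% of those moved 1.5-fold and 89.4% of those moved 2-fold.

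The effects of the 4 inhibitors were set against each other. Of the genes that rose, 231 did so with both PQR309 and idelalisib, 108 with both PQR309 and ibrutinib and 70 with both idelalisib and ibrutinib. Of the genes that fell, 186, 157 and 115 were shared by these pairs. Duvelisib had 2 rises and 0 falls, and the 2 rose with each of the other 3. The comparisons share their DMSO arrays, which can raise such overlaps, and how many would be shared without drug effects was not simulated. Across 12559 genes the mean effects correlated at r = 0.821 for PQR309 and idelalisib, 0.874 for PQR309 and duvelisib and 0.772 for PQR309 and ibrutinib. They correlated at 0.885 for idelalisib and duvelisib, 0.839 for idelalisib and ibrutinib and 0.820 for duvelisib and ibrutinib. Genes are not independent replicates, and the shared DMSO arrays alone gave r = 0.5 in 100 simulations of unchanged groups. That value follows from the equal spread that the simulation gave to both drugs and DMSO. It was not measured from these arrays, and noisier DMSO arrays would raise it. With the 2 drugs taken from different lines, so that no DMSO array was shared, the mean r over 6 partitions was 0.476, 0.444, 0.428, 0.337, 0.390 and 0.294 for the same pairs. The lowest value of a single partition was -0.0386 for duvelisib and ibrutinib and -0.0430 for idelalisib and ibrutinib.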

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

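The tests of the 3 patterns weighed below (heat shock genes, G2/M genes and the 2 sets of arrays) were chosen only after those results were seen, as was the list of heat shock genes; the splits of the lines were planned. A line was set apart where its gap to the nearest other line, divided by the whole range, passed Dixon's 95% value, which chance does in about 1 of 20 groups. Of 109 named genes 4 did so for PQR309 over 8 lines: JUNB in TMD8 (-0.58, others -0.30 to -0.07; ratio 0.554), MX2 in DOHH2 (-0.17, others 0.15 to 0.43; 0.531), ETV6 in RIVA (0.76, others 0.19 to 0.34; 0.740) and COL1A1 in DOHH2 (-0.16, others -0.02 to 0.04; 0.720). Of 27 list medians over 8 lines 2 did so, the interferon genes in TMD8 (-0.27, others -0.01 to 0.07; 0.761) and the stromal markers in DOHH2 (-0.16, others -0.01 to 0.04; 0.728). Of 108 list medians over 4 lines 8 did so. They were germinal-centre markers (0.879, U2932 at 0.22) and heat shock genes (0.836, SUDHL2 at -0.21) with PQR309, and lysosome genes with idelalisib (0.924, TMD8 at 0.19). With duvelisib they were FOXO targets (0.839, SUDHL2 at 0.03) and activated-class markers (0.867, RIVA at -0.27), and with ibrutinib G1/S genes (0.909, TMD8 at -0.16), lysosome genes (0.843, TMD8 at 0.21) and myeloid markers (0.845, RIVA at 0.11). Of 15 groups of summed raw intensities 0 did so.

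The PQR309 effect differed between 4 and 12 h for 1292 genes in limma (722 without RIVA, 748 without OCILY18, 777 without SUDHL2, 836 without SUDHL10, 839 without U2932), with RPL21P28 (0.88), LTB (0.78), FCMR (0.73), YPEL5 (0.72), PHYH (0.71), HSPE1 (-1.11), FABP5 (-0.94), GPI (-0.88), CACYBP (-0.81) and PKM (-0.81) at the ends. Among bright probes without a gene name, which no comparison used, 1011 of 6741 passed for PQR309 over the 3 times (528 rose and 483 fell), with changes up to 0.85 and down to -0.80.

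Heat shock genes were lower with PQR309. Of 20 measured members 0 rose and 16 fell, and 2 members stand in other lists too; the list's median effect averaged -0.21 at 4 h, -0.51 at 8 h and -0.56 at 12 h. A rise in the DMSO cultures between 4 and 12 h (0.38) is not the whole cause, since the effect was -0.21 (SD 0.12, n = 8) at 4 h and above 0 in 0 of 8 lines, and the PQR309 arrays themselves rose by 0.16. A difference between DMSO and PQR309 arrays within 1 hybridization is argued against by the other arrays of the 4 lines, where the mean was -0.46 (SD 0.17, 0 of 4 above 0). What happened to the cultures before the RNA was taken was not tested, so it remains open, and a lower heat shock response under PQR309 may be the biological explanation, as a hypothesis.

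G2/M genes were higher with all 4 inhibitors, in 4 of 4 lines with each. For PQR309 the DMSO arrays that the 4 comparisons share are not the whole cause. The other DMSO and PQR309 arrays of the same lines gave a mean of 0.23 (SD 0.14, above 0 in 4 of 4), and the lines given PQR309 only gave 0.11 (SD 0.06). Idelalisib, duvelisib and ibrutinib were set only against the shared DMSO arrays, so for these drugs that cause stays open. Quantile normalization is not the whole cause either: with median scaling the list's shift relative to all genes kept at least 0.676 of its size, going from 0.26 to 0.17 with PQR309, 0.22 to 0.17 with idelalisib, 0.15 to 0.20 with duvelisib and 0.21 to 0.21 with ibrutinib. A larger share of cells in G2 or mitosis may be the biological explanation, a hypothesis that these arrays cannot separate from higher levels per cell.

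PQR309 effects differed between the 2 sets of arrays, most in SUDHL2. Across genes the effects of the 2 sets correlated at 4, 8 and 12 h at 0.238, 0.588 and 0.697 in RIVA, 0.227, 0.691 and 0.751 in TMD8, 0.560, 0.624 and 0.719 in U2932, and -0.0586, -0.0404 and 0.408 in SUDHL2, while the means over the 4 lines correlated at 0.819 over 11856 genes. The dim raw SUDHL2 DMSO array at 8 h (median intensity 78.3) is not the whole cause, since the 4 h effects, which do not use it, correlated at -0.0586. Arrays exchanged between treatments or times could be a cause: 17 of 24 arrays were most like the array of the same name in the other table, 22 matched in treatment, and in SUDHL2 4 of 6 matched. This stays open, because the files do not say how the sets were made, and a biological difference between cultures is also untested.

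Other splits of the lines, or sign changes of whole lines, showed how often chance alone would give as many genes. For PQR309 over the 3 times 1 of 100 splits, the real one, did so (3295, highest other 1732). The same count, 1 of 100, was found at 4 h (2155, other 60), 8 h (1988, 761) and 12 h (2552, 1503). It was also found for the change between 4 and 12 h (1292, 134) and for DMSO between 4 and 12 h (950, 1). Chance alone is thus an unlikely source of these counts, but 100 splits cannot exclude it. The splits also cannot separate an effect of drug or time from another difference shared by all lines. With raw intensities, mostly in fewer lines, these counts were lower, as given below. For the PQR309 effect between line sets and for the DMSO line sets the real count was 0, which each of 35 splits reaches by construction (35 of 35, highest other 38 and 4), so the splits say nothing there. For the 4 lines, 8 splits are too few for a share under 0.05. Splits with as many genes numbered 1 for PQR309 (1696, highest other 0), 1 for idelalisib (586, other 1), 2 for duvelisib (2, other 3) and 1 for ibrutinib (373, other 0). Between drugs they numbered 2 for PQR309 and idelalisib (11, other 40), 1 for PQR309 and ibrutinib (7, other 0), 1 for ibrutinib and idelalisib (1, other 0), and 8, as any count of 0 must, for PQR309 and duvelisib, ibrutinib and duvelisib, and duvelisib and idelalisib (each 0, other 0). An exchanged split thus gave 40 genes for PQR309 and idelalisib, so the real 11 do not exceed what an exchange of the drugs within lines can give. Its cause was not tested. For duvelisib and idelalisib at single times they numbered 8 at 4 h (0, other 2), 8 at 8 h and 8 at 12 h (both 0, other 0).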

How the results depend on the processing

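Alternatives chosen only after the data were seen were those without the SUDHL2 8 h arrays and median scaling without them. For the 8 lines raw intensities were the planned source, and their exchange with the authors' normalized values and the choice of lines with usable raw arrays came after the files were seen. Where no cause is given below, the cause was not tested. Across the named genes and comparisons, 3991 alternative values kept their side of the threshold, 743 lost the call, 28 gained one and 1 reversed. Direction was checked only where the main or the alternative value passed, so sign changes among values that passed in neither were not counted. The 1 that reversed was PIK3CD with PQR309 at 4 h, at -0.0269 with raw intensities in 6 lines (limma adjusted p = 0.900).

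No paired analysis (the line left out as a block or pair) called 0 genes for PQR309 over the 3 times, 1 at 4 h, 0 at 8 h, 0 at 12 h, 0 for the change between 4 and 12 h and 0 for DMSO between 4 and 12 h. In the 4 lines no block gave 1 for PQR309, 0 for idelalisib, 0 for duvelisib, 0 for ibrutinib, 0 for ibrutinib against idelalisib, 0 for PQR309 against idelalisib and 0 for PQR309 against ibrutinib. The spread between lines then stands in the error.

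With raw intensities, the planned source, the counts were 1304 for PQR309 over the 3 times, 212 at 4 h, 94 at 8 h, 0 for the change between 4 and 12 h (6 lines; limma, 1058 at an unadjusted p under 0.05), 853 at 12 h (7 lines) and 22 for DMSO between 4 and 12 h (8 lines). With the authors' normalized values PQR309 in the 4 lines had 244 genes (160 shared) and ibrutinib against idelalisib 0.

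With median scaling limma called 0 genes for PQR309, idelalisib, duvelisib and ibrutinib (1050, 486, 450 and 650 at an unadjusted p under 0.05), 0 for ibrutinib against idelalisib, 0 for PQR309 against idelalisib and 0 for PQR309 against ibrutinib, and these 7 counts were also 0 without the SUDHL2 8 h arrays. The median SD between lines was 0.264 for PQR309, 0.202 for idelalisib (0.169 without the SUDHL2 8 h arrays), 0.429 for duvelisib and 0.384 for ibrutinib, against 0.148, 0.167, 0.174 and 0.162 after quantile normalization, while YPEL3 and TNF kept their direction. Median scaling moved the median of all genes by over 0.1 for PQR309 against duvelisib, to -0.10. It turned the sign of the PQR309 medians of B-cell identity (0.01 to -0.05) and germinal-centre markers (0.03 to -0.02), the ibrutinib median of B-cell identity (0.01 to -0.02), and the duvelisib medians of G1/S, plasma cell and stromal genes. Between drugs it turned the sign of 10 of 27 list medians for duvelisib against idelalisib, 2 for ibrutinib against idelalisib, 8 for ibrutinib against duvelisib, and 3, 6 and 8 for PQR309 against idelalisib, duvelisib (G2/M genes, 0.12 to -0.01) and ibrutinib.

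In a fit of only the 2 treatments compared the counts were 0 for PQR309, 0 for idelalisib, 0 for duvelisib, 0 for ibrutinib, 0 for ibrutinib against idelalisib, 0 for PQR309 against idelalisib and 64 for PQR309 against ibrutinib. Without the 4 h arrays they were 1 for duvelisib, 0 for PQR309 against idelalisib and 1 against ibrutinib. Without the 8 h arrays they were 943 for PQR309, 12 for idelalisib, 0 for duvelisib, 1 for ibrutinib, and 0 for PQR309 against idelalisib and 0 against ibrutinib. Without the 12 h arrays they were 1054 for PQR309, 45 for duvelisib, 2 for ibrutinib against idelalisib, and 23 and 41 for PQR309 against idelalisib and ibrutinib. Without the SUDHL2 8 h arrays they were 0 for duvelisib, 171 for ibrutinib and 14 for PQR309 against ibrutinib. With no filter ibrutinib had 66; with the brightest 25% of probes PQR309 against ibrutinib had 15; with averaged probes duvelisib had 0, and PQR309 had 7 against idelalisib and 4 against ibrutinib.

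Leaving out each line gave 2584 to 3393 genes for PQR309 over the 3 times, 1303 (without RIVA) to 2206 at 4 h, 1216 (without U2932) to 2177 at 8 h, 1637 (without U2932) to 2680 at 12 h, 722 (without RIVA) to 1437 for the change with time, 339 (without RIVA) to 902 for DMSO over time and 0 to 3 (without U2932) for the DMSO line sets. In the 4 lines it gave 294 (without TMD8) to 2033 for PQR309, 0 (without RIVA or TMD8) to 435 for idelalisib, 0 (without RIVA or TMD8) to 108 (without SUDHL2) for duvelisib, 2 (without RIVA or TMD8) to 473 for ibrutinib, 0 (without SUDHL2 or U2932) to 1 for ibrutinib against idelalisib, 0 to 0 for PQR309 against idelalisib, 0 (without RIVA or U2932) to 9 for PQR309 against ibrutinib and 0 to 89 (without TMD8) for duvelisib against idelalisib at 4 h. Of the 12 lists past camera for PQR309 over the 3 times, 0 passed with an estimated correlation, 12 with fry and 10 to 13 with a line left out. The correlations between drug effects lay from 0.651 to 0.915 under the alternatives. Not run were another background correction and scaling for the 8 lines, whose values were already normalized, the chip as a block (no array positions are given), and the authors' values for contrasts across their 2 sets. Signal over background limits genes near the detection level, at 6.73 and 6.27 log2 units.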

Other observations

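No list fixed beforehand was one of heat shock genes; this list and its tests were made only after its members HSPA1B, HSPA8 and HSPH1 were seen among the largest falls. In the 4 lines the heat shock list's median effect averaged -0.46 (SD 0.17, n = 4) with PQR309, -0.17 (SD 0.14) with idelalisib, -0.17 (SD 0.16) with duvelisib and -0.12 (SD 0.13) with ibrutinib. HSPA1B, the inducible chaperone, fell by 0.63 ± 0.13 (SE, n = 4) with PQR309 and was at -0.10 ± 0.13 with idelalisib, -0.20 ± 0.13 with duvelisib and -0.11 ± 0.13 with ibrutinib. HSPA8, its constitutive relative, fell by 0.75 ± 0.09 with PQR309 and was at -0.31 ± 0.09, -0.37 ± 0.09 and -0.24 ± 0.09 with the other 3. Compared within lines and relative to all genes, the list's median with PQR309 lay at -0.24 against idelalisib, -0.26 against duvelisib and -0.29 against ibrutinib. With median scaling these values were -0.25, -0.36 and -0.36. The difference between PQR309 and these inhibitors was not tested for this list.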
